A study of Mus musculus with 6 samples.

How the data were processed

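Total RNA of DP42 murine myeloma cells was hybridised to Affymetrix arrays after 24 h of culture alone, with mouse B cells or with mouse neutrophils, with 2 arrays in each of the 3 groups. Per the labels' protocols, flow cytometry separated the co-cultured populations, the cells were washed and lysed in Trizol, and the RNA was labelled with biotin in the manner usual for Affymetrix arrays. The array model is not given in the sources used here, nor are the software version and annotation build behind the values.

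The deposited table held log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA (robust multi-array average) subtracts background, normalises between arrays and summarises the probes of a probe set on the log2 scale. Values ran from 3.04 to 14.03 and array medians from 7.09 to 7.22, and the scale was taken as log2 from the values. Whether any further centring was done is not stated. Normalisation between arrays assumes similar overall distributions, so a change shared by most genes would not be visible, and signals near background are compressed. The number of arrays limits the precision, and no detection call per probe set was used.

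Of 41345 probe sets, 23521 were named with 1 gene in the platform annotation, 1814 with several genes and 16010 were unnamed here, of which 190 were Affymetrix control rows. Probe sets with several genes or no name were not used for gene results. Of those named with 1 gene, 23328 had their gene identifier in the reference gene table of GRCm38.p6, and their symbols differed from that table in 0 cases. For the 1082 genes with several probe sets the probe set with the highest mean over the 6 arrays was kept, leaving 22180 genes. No coordinates are given, because the table names no genome build.

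Groups were taken from the co-culture label of each sample. Group means were fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays, which share an estimate of the spread with 3 residual degrees of freedom and a prior of 5.55. Moderated statistics came from eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The 3 contrasts tested were neutrophil co-culture minus B-cell co-culture, neutrophil co-culture minus culture alone, and B-cell co-culture minus culture alone. A gene is called changed below when it passed that threshold, and differences are on the log2 scale, given as the first group minus the second.

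Before the data were examined, 30 gene lists were fixed: 22 of cell responses, 1 of plasma cell identity and 7 of markers of other cell types. They held 763 symbols, of which 680 were measured, after older symbols were matched through the reference table. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists of a contrast. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move 1 way on balance, were alternatives.

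The rule for genes named in the text was also fixed before the data were examined, and genes named outside it are said to have been chosen after their values were seen. Per contrast and direction it took the 12 called genes with the largest difference whose arrays did not overlap between the groups. Where fewer than 6 passed, it was filled to 6 with genes at an unadjusted p under 0.05 and non-overlapping arrays, which are said not to pass. Predicted or clone genes and immunoglobulin or T cell receptor segments were skipped. It added the 4 members with the largest difference in the direction of each called list, and 27 fixed genes of neutrophils, B cells, plasma cells and signalling, of which 25 were analysed and the rest are not reported here.

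The procedure was tested on simulated data of the same size, with 200 of 22180 genes changed in neutrophil co-culture minus culture alone, in 20 simulations. It recovered 79.3% of genes changed 1.5-fold, 99.9% of those changed 2-fold and 100% of those changed 4-fold, with 8.80% false genes among the calls. With no change simulated, a mean of 0.05 of 90 list tests passed. Noise was drawn independently for each gene, so these simulations cannot show the error of the tests where genes vary together between arrays.

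Alternatives chosen beforehand were a filter on dim genes, eBayes with trend and robust settings, quantile normalisation of the deposited values, centring on array medians, averaging of probe sets, fits of only 4 arrays, the replicate number as a block, leaving out each array, other thresholds and all probe sets. Added after seeing the data were the array mean of 1394 olfactory and vomeronasal receptor genes as a covariate, and leaving those genes out. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.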

Results

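Gene expression was measured in DP42 cells, a murine line of multiple myeloma, which is a cancer of plasma cells. The cells were cultured for 24 h alone, with mouse B cells or with mouse neutrophils, and co-cultured cells were sorted by flow cytometry before RNA extraction. The labels call the neutrophils "neutrophils (IMC)" and the array titles "IMCs", which the sources used here do not spell out. Each group held 2 arrays. The design text calls the B-cell co-culture the control, and the title of the series concerns an effect of marrow neutrophils, and of DNA they release, on myeloma. Nothing in the labels says whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

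The titles of the co-culture arrays name the partner cell, while their other labels name DP42 cells, so cell type markers were read first. Pax5, a transcription factor of the B lineage, stood at 10.98 ± 0.03 in cells cultured alone, 10.95 ± 0.02 with B cells and 11.03 ± 0.06 with neutrophils (log2, mean ± SD, n = 2). Irf4, a regulator of plasma cells, stood at 10.79 ± 0.07, 10.74 ± 0.08 and 10.92 ± 0.08, and Xbp1, which drives the secretory programme of plasma cells, at 10.03 ± 0.05, 10.02 ± 0.18 and 10.17 ± 0.01. The plasma cell surface proteoglycan Sdc1 stood at 8.49 ± 0.09, 8.49 ± 0.16 and 8.60 ± 0.10. The other fixed plasma cell genes were dimmer and lay below the array medians in both co-cultures. Prdm1 stood at 6.81 ± 0.05 with B cells and 6.96 ± 0.02 with neutrophils, and Tnfrsf17 at 6.13 ± 0.15 and 5.82 ± 0.11. The plasma cell identity list did not pass in any contrast, with adjusted p = 0.369 for neutrophils against B cells, 0.320 for neutrophils against alone and 0.818 for B cells against alone. The mature B cell list did not pass either, with adjusted p = 0.191, 0.112 and 0.710. Its array means were already 9.98 and 9.94 in cells cultured alone, where Pax5 was high too, so neither says much about carried B cells. Ms4a1, the gene of CD20, stood at 6.33 ± 0.00 in cells cultured alone and 6.33 ± 0.27 in cells cultured with B cells.

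Across genes, which are not independent replicates, the arrays of a group correlated at r = 0.997 for culture alone, 0.992 with B cells and 0.997 with neutrophils. B-cell replicate 1 correlated with neutrophil replicate 1 at 0.996, above its correlation with its own replicate. A first principal component, with 67.2% of the variance, placed the alone arrays at -14.7 and -12.3, the B-cell arrays at 5.17 and -27.3, and the neutrophil arrays at 21.2 and 28.0.

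The first comparison asked what neutrophils changed in the myeloma cells relative to B cells. In limma's test 11 genes changed, 7 higher and 4 lower with neutrophils. The largest log2 difference among the genes that rose was in Ly6c2 (probe set 17318100), which encodes a surface antigen of myeloid cells and some lymphocytes, at 7.13 ± 0.01 against 5.61 ± 0.12, a difference of 1.51 ± 0.10 (SE), or 2.86-fold (adjusted p = 0.00346). Ngp (17522369), which encodes a neutrophil granule protein, rose 2.76-fold (difference 1.46 ± 0.15, adjusted p = 0.0220). Ly6c2 and Ngp lay below the lower quartile of every alone and B-cell array (6.04 to 6.15), where signal was not shown to exceed background and differences are compressed, so their folds are not exact. The other 5 are genes induced by type I interferon, 4 of them, all but Ifi27, on the fixed list of that response. Ifi27 (17278200) rose 2.42-fold (1.27 ± 0.11, adjusted p = 0.0154), and Oas2 (17452054), which makes the second messenger that activates RNase L, rose 2.11-fold (1.08 ± 0.12, adjusted p = 0.0336). Usp18 (17462437), a deconjugase of ISG15 and inhibitor of interferon receptor signalling, rose 1.89-fold (0.92 ± 0.10, adjusted p = 0.0280). Irf9 (17300591), the DNA-binding subunit of the interferon-activated complex ISGF3, also rose 1.89-fold (0.92 ± 0.09, adjusted p = 0.0211), and Cmpk2 (17274620), a mitochondrial nucleotide kinase, rose 1.68-fold (0.75 ± 0.09, adjusted p = 0.0471).

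**Figure D1:**
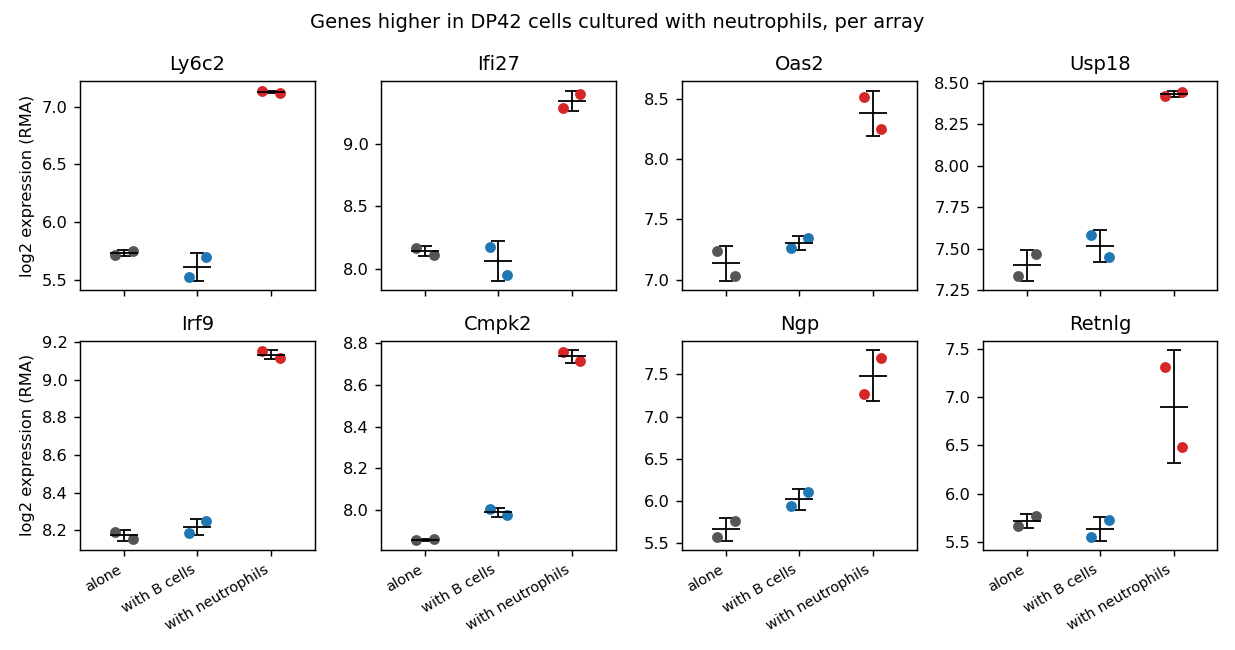
Log2 expression (RMA, vertical axis) of 8 genes in the 6 arrays, by culture group (horizontal axis). Points are arrays, horizontal marks the mean of 2 arrays and bars ± 1 SD. In each panel both neutrophil arrays lie above the other 4, as for Ly6c2 at 7.13 ± 0.01 against 5.61 ± 0.12 with B cells, and the axes do not start at 0. The genes were taken by a rule that asks for non-overlapping arrays, so this separation is not further support. Of all genes, 56.7% did not overlap, in either direction, between neutrophils and B cells, and 63.0% between neutrophils and alone.

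Among the fixed lists, the type I interferon response was the one with the largest median. Of its 26 measured genes 4 rose singly over all genes tested and 0 fell, while 17 were higher and 1 lower when adjusted over the list alone. The 4 became 17 without B-cell replicate 1 and 0 in limma without any other single array, with 16 or 17 of its genes higher at an unadjusted p under 0.05. It became 1 with quantile normalisation and 0 with the array mean of olfactory and vomeronasal receptor genes (the receptor mean) as a covariate, where 10 were higher at an unadjusted p under 0.05. The list rose by a median of 0.48, with 21 of 26 genes positive (camera adjusted p = 3.84e-10, adjusted p = 0.143 with an estimated correlation, fry adjusted p = 0.00816). Bst2, which tethers budding virus at the cell surface, stood 0.79 ± 0.16 higher (adjusted p = 0.126) and did not pass. Members were not alike: Mx1 stood 0.68 higher (adjusted p = 0.113) and Ifih1 0.57 higher (adjusted p = 0.142), while Ifit3 stood at -0.53 (adjusted p = 0.210), Rsad2 at -0.20 (adjusted p = 0.357) and Irf7 at 0.13 (adjusted p = 0.422), all short of the threshold and, with Irf7 apart, named after their values were seen. The array means of the list were 7.55 and 7.59 for culture alone, 7.61 and 7.58 with B cells, and 8.003 and 7.976 with neutrophils.

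The cholesterol and sterol synthesis list rose by a median of 0.27, with 21 of 21 genes positive (camera adjusted p = 5.56e-09, adjusted p = 0.570 with an estimated correlation). In limma 0 of its genes passed over all genes tested, and 12 were higher when adjusted over the list alone. The list kept its call without each single array, among brighter genes, with quantile normalisation and with the receptor mean as a covariate (median 0.16), and lost it with fry (adjusted p = 0.123). The largest differences were 0.63 ± 0.11 for Hmgcs1 and 0.56 ± 0.13 for Fdft1, enzymes of the mevalonate pathway and of squalene synthesis, 0.52 ± 0.11 for the sterol carrier Stard4 and 0.50 ± 0.12 for Cyp51, with adjusted p of 0.117, 0.142, 0.125 and 0.142.

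The neutrophil marker list rose by a median of 0.11, with 21 of 33 genes positive (camera adjusted p = 0.0161, adjusted p = 0.570 with an estimated correlation). Ngp passed over all genes tested, and 6 genes were higher when adjusted over the list alone. The list did not pass among brighter genes, 7 of its genes being left (adjusted p = 0.846). Without B-cell replicate 1 the list did not pass (median 0.09, adjusted p = 0.580) while 6 of its genes did, and 0 passed in limma without either alone replicate or B-cell replicate 2 (8 higher at an unadjusted p under 0.05). The resistin-like gene Retnlg stood 1.27 ± 0.23 higher (adjusted p = 0.117), S100a8 0.73 ± 0.10 (adjusted p = 0.072), the cathelicidin gene Camp 0.67 ± 0.16 (adjusted p = 0.144) and Lcn2, which binds bacterial siderophores, 0.55 ± 0.11 (adjusted p = 0.125). The differences were 0.08 ± 0.17 for S100a9, the partner of S100a8 in calprotectin, 0.18 ± 0.11 for lactoferrin, Ltf, and 0.26 ± 0.10 for lysozyme, Lyz2, none of which passed. Retnlg, S100a8 and Camp lay below the lower quartile of both B-cell arrays, so the size of their differences is not exact.

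A further 13 lists rose relative to all genes, in each case with adjusted p = 0.570 with an estimated correlation. Genes at or above the median brightness had a median of 0.13 in this comparison, against 0.01 for all genes, and among those brighter genes 0 of the 13 lists passed (camera, medians 0.12 to 0.19). With quantile normalisation 1 of the 13 passed, immediate early genes. Without B-cell replicate 2 their medians were 0.012 to 0.108 and 8 lost the call, namely interferon gamma, pro-apoptotic genes, p53 targets, mitosis, the unfolded protein response, hypoxia, autophagy and heat shock. Without neutrophil replicate 2 pro-apoptotic genes and autophagy lost it, and with the receptor mean as a covariate 0 of the 13 kept it and 10 medians turned negative. In limma's test 0 of their members passed over all genes tested, and adjusted over the list alone only the interferon gamma list had any, 2 higher and 1 lower. Growth lists were among them: DNA replication and S phase had a median of 0.14 with 32 of 32 genes positive (adjusted p = 3.86e-05; Gins1 0.34 ± 0.15, Gins2 0.33 ± 0.11), mitosis 0.12 with 34 of 35 (adjusted p = 0.00087; Birc5 0.32 ± 0.13), and MYC targets and ribosome synthesis 0.15 with 31 of 31 (adjusted p = 7.95e-05; Tcof1 0.29 ± 0.11). Energy metabolism lists were oxidative phosphorylation, at 0.17 with 33 of 33 genes positive (adjusted p = 6.9e-05; Cox5a 0.34 ± 0.15), and hypoxia and glycolysis, at 0.12 with 26 of 32 (adjusted p = 0.0026; Hk2 0.39 ± 0.12). Stress lists were the unfolded protein response, at 0.13 with 25 of 29 (adjusted p = 0.0026; the chaperone Dnajb9 0.46 ± 0.11), heat shock, at 0.16 with 13 of 14 (adjusted p = 0.0088; Hspa1b 0.39 ± 0.11), p53 targets, at 0.11 with 22 of 26 (adjusted p = 0.013; Plk3 0.50 ± 0.12), pro-apoptotic genes, at 0.10 with 15 of 18 (adjusted p = 0.031; Bbc3, the gene of PUMA, 0.32 ± 0.11), and autophagy and lysosome, at 0.11 with 22 of 26 (adjusted p = 0.016; Npc1 0.34 ± 0.11). The remaining 3 were immediate early genes, at 0.13 with 23 of 27 (adjusted p = 0.0011; Dusp1 0.34 ± 0.10), interferon gamma and antigen presentation, at 0.16 with 20 of 26 (adjusted p = 0.0088; the GTPase gene Igtp 0.62 ± 0.15), and adhesion, at 0.12 with 20 of 25 (adjusted p = 0.0088; the integrin Itgb1 0.33 ± 0.12). In all 13 the mean of B-cell replicate 1 lay above that of replicate 2, as in DNA replication with 10.65 against 10.46, beside 10.71 and 10.74 with neutrophils and 10.56 and 10.55 alone.

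The other 14 lists did not pass. Adjusted p was 0.0553 for the ATF4 amino acid response, 0.0574 for JAK-STAT3 targets, 0.102 for DNA and nucleic acid sensing, 0.145 for anti-apoptotic genes, 0.250 for NRF2, 0.512 for NF-kB targets and 0.513 for cytokines and chemokines. Marker lists of other cells stood at 0.102 for eosinophils, basophils and mast cells, 0.274 for T and NK cells, 0.507 for dendritic cells, 0.876 for erythroid cells and megakaryocytes and 0.896 for monocytes and macrophages, the last with a median of -0.03, a mean of 0.04 and an upward test. Ly6c2 is a member of that monocyte list, and no other member of these 14 lists passed over all genes tested. Adjusted over the list alone, 1 mature B cell gene and 2 T and NK cell genes were lower, and 1 monocyte and 2 dendritic cell genes were higher. Fixed regulators did not pass: Tlr9, an endosomal receptor for DNA, stood 0.17 ± 0.09 higher, Myc 0.04 ± 0.10, Mcl1 0.16 ± 0.12, Bcl2 0.03 ± 0.09, Bcl2l1 -0.02 ± 0.11, Cdkn1a 0.11 ± 0.10, Nfkbia 0.13 ± 0.12 and Socs3 0.00 ± 0.09.

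The 4 genes that fell were olfactory receptors: Olfr1275 by a difference of -1.18 ± 0.11 (adjusted p = 0.021), Olfr111 at -1.09 ± 0.11 (adjusted p = 0.022), Olfr347 at -1.05 ± 0.10 (adjusted p = 0.021) and Olfr952 at -0.81 ± 0.10 (adjusted p = 0.0497). All but Olfr347 lay below the lower quartile of all 6 arrays, so the size of their differences is not exact. The multicopy testis genes Srsy at -3.05 ± 0.47 (adjusted p = 0.099) and Astx5 at -2.72 ± 0.44 (adjusted p = 0.11) did not pass. With arrays centred on their medians the split was 45 higher and 90 lower. The count of 11 became 5453 without B-cell replicate 1, 1 without B-cell replicate 2 or either alone replicate and 2 without neutrophil replicate 2, and 0 in limma with the receptor mean as a covariate (777 at an unadjusted p under 0.05), while the 16 lists became 8 without B-cell replicate 2.

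The second comparison set neutrophil co-culture against culture alone, and 331 genes changed, 29 higher and 302 lower. The split was 21 higher and 69 lower among genes at or above the median brightness, 23 and 86 without the olfactory and vomeronasal receptor genes, and 11 and 59 with quantile normalisation. Of the 29, 11 were on the type I interferon list and 5 on the neutrophil list. Ngp rose 3.53-fold (1.82 ± 0.15, adjusted p = 0.00498), Ly6c2 2.63-fold (1.40 ± 0.10, adjusted p = 0.00226), Oas2 2.38-fold (1.25 ± 0.12, adjusted p = 0.00862), Ifi27 2.29-fold (1.20 ± 0.11, adjusted p = 0.00741) and Retnlg 2.28-fold (1.19 ± 0.23, adjusted p = 0.0459). Retnlg, like Ly6c2, Ngp and S100a8, lay below the lower quartile of both alone arrays, so these folds too are not exact. Ifi214, of the interferon-induced p200 family, rose 2.08-fold (1.06 ± 0.13, adjusted p = 0.0176), Usp18 2.05-fold (1.03 ± 0.10), Irf9 1.95-fold (0.96 ± 0.09) and Cmpk2 1.84-fold (0.88 ± 0.09). Mir3094 (0.93 ± 0.18), BC147527 (0.75 ± 0.12) and the pro-apoptotic interferon-induced gene Xaf1 (0.75 ± 0.12) were the rest of the 12 genes with the largest rise under the naming rule.

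The type I interferon list rose by a median of 0.46, with 23 of 26 genes positive (camera adjusted p = 1.31e-11, adjusted p = 0.118 with an estimated correlation, fry adjusted p = 0.00633). Singly 11 of its genes rose and 0 fell over all genes tested, and 16 were higher when adjusted over the list alone. The 11 became 0 in limma without either alone replicate (14 higher at an unadjusted p under 0.05), 4 without neutrophil replicate 1, 1 without neutrophil replicate 2 and 5 with quantile normalisation, and 0 with the receptor mean as a covariate (8 higher at an unadjusted p under 0.05). Besides the genes above these were Xaf1, Oasl2 at 0.67, Mx1 at 0.64, Oasl1 at 0.61, Ddx58, the RNA sensor RIG-I, at 0.59, Parp14 at 0.57 and Dhx58 at 0.51, with adjusted p from 0.0281 to 0.0490. Ifit1 at -0.25, Ifit3 at -0.38 and Rsad2 at -0.12 did not pass. Of these genes all but Xaf1 were named after their values were seen.

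The neutrophil list rose by a median of 0.15, with 25 of 33 genes positive (camera adjusted p = 0.00103, adjusted p = 0.706 with an estimated correlation). Over all genes tested 5 of its members rose, Ngp, Retnlg, Lcn2 at 0.68 ± 0.11 (adjusted p = 0.0323), S100a8 at 0.61 ± 0.10 (adjusted p = 0.0321) and Elane, neutrophil elastase, at 0.55 (adjusted p = 0.0373), which was named after its value was seen. The 5 became 0 in limma without alone replicate 1 (7 higher at an unadjusted p under 0.05), 1 without alone replicate 2 or neutrophil replicate 1, 2 without neutrophil replicate 2, 3 with quantile normalisation and 0 with the receptor mean as a covariate (10 higher at an unadjusted p under 0.05), where the median was 0.32. Among brighter genes the list did not pass (adjusted p = 0.733). Adjusted over the list alone 7 were higher and 1 lower. S100a9 at 0.15 ± 0.17, Ltf at 0.23 ± 0.11, Camp at 0.40 ± 0.16 and Lyz2 at 0.38 ± 0.10 did not pass. Of the B-cell genes Cr2, the complement receptor CD21, stood at -0.61 ± 0.13 (adjusted p = 0.061) and did not pass.

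A further 11 lists rose relative to all genes, in each case with adjusted p = 0.706 with an estimated correlation and with 0 members rising over all genes tested. Genes at or above the median brightness had a median of 0.11 against 0.02 for all genes, and among them 2 of the 11 passed, DNA replication and cholesterol synthesis. With quantile normalisation 3 passed, these and immediate early genes. With the receptor mean as a covariate 0 of the 11 kept the call and 9 medians turned negative, 2 of them past the threshold, the unfolded protein response and hypoxia. The call was lost by 5 lists without alone replicate 2 (interferon gamma, p53, MYC, hypoxia and adhesion), by oxidative phosphorylation without alone replicate 1, by oxidative phosphorylation and adhesion without neutrophil replicate 1, and by interferon gamma, hypoxia and adhesion without neutrophil replicate 2. Cholesterol synthesis had a median of 0.22 with 20 of 21 genes positive (adjusted p = 9.31e-06; Fdft1 0.50 ± 0.13, Lss 0.39 ± 0.10) and 4 genes higher when adjusted over the list alone. DNA replication had a median of 0.18 with 32 of 32 (adjusted p = 1.2e-05; Cdc6 0.34 ± 0.11), mitosis 0.14 with 34 of 35 (adjusted p = 4.6e-05; Hmmr 0.32 ± 0.11) and MYC targets 0.09 with 29 of 31 (adjusted p = 0.0086; Polr1e 0.31 ± 0.10). Immediate early genes had 0.10 with 25 of 27 (adjusted p = 0.0032; Egr1 0.33 ± 0.12), the unfolded protein response 0.10 with 26 of 29 (adjusted p = 0.016; Dnajb9 0.46 ± 0.11), and interferon gamma and antigen presentation 0.13 with 20 of 26 (adjusted p = 0.027; Irgm1 0.46 ± 0.14). Adjusted over the list alone, the last had 1 higher and 1 lower gene. Its member Iigp1, a GTPase gene, fell by 0.78 ± 0.12 (adjusted p = 0.0264) and was named after its value was seen. P53 targets, hypoxia and glycolysis, and oxidative phosphorylation had medians of 0.10, 0.10 and 0.09 (adjusted p = 0.027 each), and adhesion had 0.07 (adjusted p = 0.048).

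The other 17 lists did not pass in this comparison. Beside the plasma and B cell lists, adjusted p was 0.0511 for autophagy, 0.112 for pro-apoptotic genes, 0.118 for the ATF4 response and heat shock, 0.180 for DNA sensing, 0.243 for JAK-STAT3, 0.366 for anti-apoptotic genes, 0.500 for NF-kB, 0.563 for NRF2 and 0.817 for cytokines. It was 0.126 for eosinophil, 0.665 for T and NK cell, 0.817 for erythroid, 0.817 for dendritic cell and 0.820 for monocyte markers. The dendritic cell list had a median of 0.04, a mean of -0.02 and a downward test, and the monocyte list a median of -0.02, a mean of 0.01 and a downward test. Over all genes tested Ly6c2 of the monocyte list rose, and Ifi205 of the DNA sensing list, named after its value was seen, fell by 0.75 ± 0.13.

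Among the 302 genes that fell were 144 olfactory receptors, 37 vomeronasal receptors, 23 predicted genes, 5 Speer genes and 3 keratin-associated proteins. Of 1105 olfactory receptor genes 94.2% were lower with neutrophils than alone, with a median of -0.39, and the median was -0.30 against B cells. Vomeronasal receptors (289 genes) had medians of -0.32 and -0.27. Both families kept their direction with quantile normalisation (-0.30 and -0.24 against alone) and with centring (-0.32 and -0.25). The naming rule, which passes over predicted genes, took Srsy (-3.50 ± 0.47, adjusted p = 0.021), Vmn1r129 (-3.25 ± 0.36), Pla2g10os (-3.18 ± 0.53), Sly (-3.16 ± 0.45), Astx5 (-3.15 ± 0.44), Mir101c (-3.12 ± 0.52), Speer4cos (-2.61 ± 0.36), Vmn1r91 (-2.47 ± 0.40), BC061237 (-2.30 ± 0.37), Vmn1r127 (-2.29 ± 0.31), Vmn1r103 (-2.25 ± 0.35) and Mir680-1 (-2.20 ± 0.42), many of them members of multicopy families with near-identical copies, for which a probe set may not separate the genes. Vmn1r129, Pla2g10os and Sly lay below the lower quartile of both neutrophil arrays, so the size of their differences is not exact. The mean of the 1394 receptor genes per array was 5.56 and 5.51 alone, 5.27 and 5.59 with B cells, and 5.13 and 5.05 with neutrophils, so that B-cell replicate 1 lay between the other groups.

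**Figure D2:**
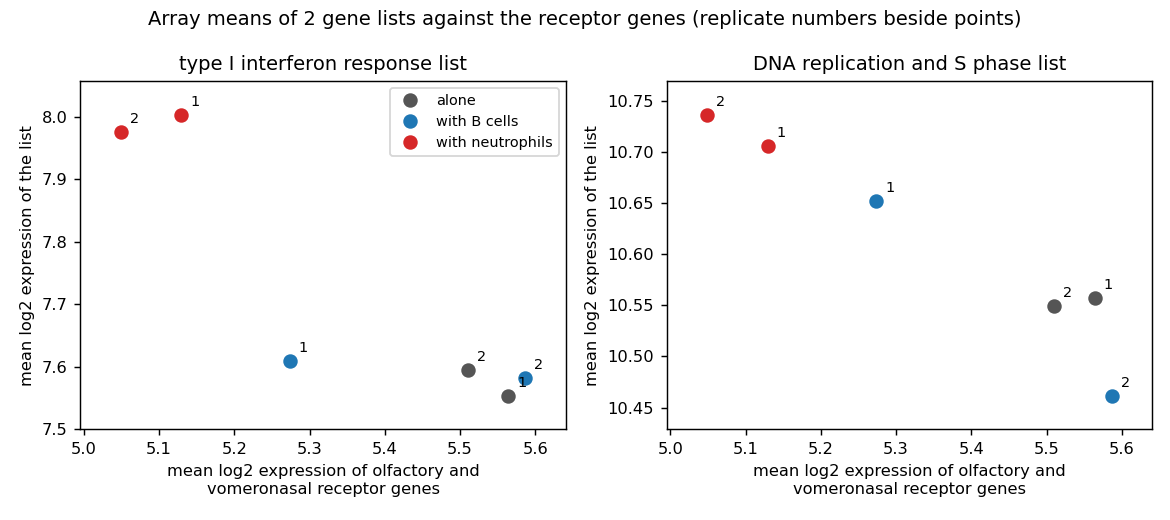
Mean log2 expression per array of the type I interferon list (left) and the DNA replication list (right) against the mean log2 expression of 1394 olfactory and vomeronasal receptor genes; each point is 1 array, coloured by group, with its replicate number. B-cell replicate 1, at 5.27 on the horizontal axis, lies with the alone arrays for the interferon list (7.61) and nearer the neutrophil arrays for DNA replication (10.65).

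The 331 calls depended on single arrays, with 5 without alone replicate 1, 7 without alone replicate 2, 113 without neutrophil replicate 1, 9 without neutrophil replicate 2 and 1338 without either B-cell replicate. With the receptor mean as a covariate 0 genes passed in limma (1254 at an unadjusted p under 0.05), and the 13 lists became 8 without alone replicate 2.

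All 11 genes called against B cells were also called against alone in the same direction, 7 higher and 4 lower. Independent lists of these sizes would share 0.00915 higher and 0.0545 lower genes. The comparisons share the neutrophil arrays, and with no effect simulated they shared a mean of 0.11 genes and at most 1 in 100 simulations. Noise in these was drawn independently for each gene, so a deviation of the neutrophil arrays common to many genes was not simulated. Groups of 2 arrays cannot be split further, so part of the excess may come from the shared arrays. The 11 became 1174 without B-cell replicate 1, 1 without B-cell replicate 2 or either alone replicate and 2 without neutrophil replicate 2, and with centring 108, 25 higher and 83 lower.

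The third comparison asked what B cells changed relative to culture alone. In limma's test 0 genes changed, with 869 at an unadjusted p under 0.05 and a smallest adjusted p of 0.239. The interferon list had a median of 0.06 (adjusted p = 0.598) and the neutrophil list 0.05 (adjusted p = 0.276). Ngp stood 0.36 ± 0.15 higher, Oas2 0.17 higher and S100a8 at -0.12 ± 0.10, none passing. The largest differences with non-overlapping arrays did not pass either: Olfr775 (0.71), Nlrp4g (0.69), Mir301b (0.57), Sprr2d (0.55), Twist2 (0.55) and Prl8a8 (0.50) stood higher, and Mir450-2 (-1.18), Snora15 (-1.18), Rnu3a (-1.16), Olfr1307 (-1.13), Olfr350 (-0.98) and Olfr1383 (-0.93) lower, with adjusted p from 0.47 upward.

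With B cells 2 lists fell. Oxidative phosphorylation fell by a median of 0.05, with 9 of 33 genes positive (Ndufa1 -0.33 ± 0.10, Cox4i1 -0.28 ± 0.12), and cholesterol synthesis fell by a median of 0.07, with 6 of 21 positive (Stard4 -0.27 ± 0.11, Insig1 -0.24 ± 0.11), both with adjusted p = 0.0359, and adjusted p = 0.940 with an estimated correlation. The other 28 lists had adjusted p of 0.276 or above, and in 5 of them the median differed in sign from the test. In the 2 lists that fell, 0 genes passed in limma, over all genes tested or adjusted over the list alone. Among the other 28 lists, 1 dendritic cell gene was lower when adjusted over the list alone, Cd209a at -0.83 ± 0.10, named after its value was seen (adjusted p = 0.239 over all genes). The 2 lists became 16 without B-cell replicate 1 (2 up, 14 down), 3, all up, without B-cell replicate 2, and 0 without either alone replicate or either neutrophil replicate.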

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

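The receptor covariate and leaving out the receptor genes were chosen after seeing the data, the other alternatives before. Within groups the receptor mean differed most between the B-cell arrays (5.27 and 5.59). It was 5.56 and 5.51 alone and 5.13 and 5.05 with neutrophils, so values with this covariate rest mostly on the 2 B-cell arrays. Single genes were followed only if the naming rule took them, 26 of the 331 called against alone and all 11 called against B cells. Of their values under alternatives chosen before, 291 stayed on their side of the threshold and 211 fell short of it. Of values of called lists 317 stayed, 147 fell short and 1 reversed. Signal over background, which no detection call measures here, limits what the dim receptor genes can show. A group with 1 array left is assumed to vary like the others. The cause was not tested except where fewer arrays, fewer genes or another threshold define the alternative.

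The 11 genes of neutrophils against B cells became 91 among genes at or above the median brightness, 33 with trend and robust settings, 7 with quantile normalisation, 135 with centring, 0 with the receptor covariate (777 at an unadjusted p under 0.05 in limma), 1 with only 4 arrays, 30 at an adjusted p under 0.10, 1 under 0.01, 0 over all probe sets (7231 at an unadjusted p under 0.05), 7 at 2-fold or more and 4449 at an unadjusted p under 0.05. Leaving out single arrays gave 1 (either alone replicate or B-cell replicate 2) to 5453 (B-cell replicate 1), and 2 without neutrophil replicate 2. With the replicate number as a replicate block the count was 9, 8 of them among the 11. The replicate numbers carried no shared signal across genes, with r = -0.0742 for alone and B cells, 0.0651 for alone and neutrophils and -0.151 for B cells and neutrophils. The 16 lists became 2 among brighter genes, 4 with quantile normalisation, 4 with the covariate, 0 with an estimated correlation and 1 with fry, and 8 (B-cell replicate 2) to 19 (B-cell replicate 1, 18 up and 1 down) without single arrays.

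The 331 genes of neutrophils against alone became 90 among brighter genes, 70 with quantile normalisation, 581 with centring, 0 with the covariate (1254 at an unadjusted p under 0.05 in limma), 109 without the receptor genes, 1338 with only 4 arrays, 750 at an adjusted p under 0.10, 14 under 0.01, 0 over all probe sets (7092 at an unadjusted p under 0.05), 131 at 2-fold or more and 3923 at an unadjusted p under 0.05. Leaving out single arrays gave 5 (alone replicate 1) to 1338 (either B-cell replicate), with 7 without alone replicate 2, 113 without neutrophil replicate 1 and 9 without neutrophil replicate 2. The 13 lists, all up, became 4 among brighter genes (3 up, 1 down), 5 with quantile normalisation, 7 with the covariate (3 up, 4 down), 8 without the receptor genes, 7 at an adjusted p under 0.01, 0 with an estimated correlation and 1 with fry, and 8 (alone replicate 2) to 14 without single arrays.

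The 0 genes of B cells against alone became 1 among brighter genes, 1 with trend and robust settings, 3 with centring and 869 at an unadjusted p under 0.05, and stayed at 0 to 0 without single arrays. The 2 lists became 0 among brighter genes, 0 with quantile normalisation, 0 with centring, 1 with probe sets averaged, 0 with the replicate block, 9 with the covariate (1 up, 8 down), 0 with only 4 arrays, 0 at an adjusted p under 0.01, 0 with an estimated correlation and 0 with fry, and 0 (either alone or neutrophil replicate) to 16 (B-cell replicate 1, 2 up and 14 down) without single arrays.

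The 11 genes shared by both neutrophil contrasts became 54 among brighter genes, 27 with trend and robust settings, 7 with quantile normalisation, 108 with centring, 0 with the covariate, 28 at an adjusted p under 0.10 and 1 under 0.01. Leaving out single arrays gave 1 (either alone replicate or B-cell replicate 2) to 1174 (B-cell replicate 1), and 2 without neutrophil replicate 2.

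With the receptor covariate these medians of neutrophils against B cells reversed: immediate early and AP-1 -0.0512, pro-apoptotic -0.0415, p53 targets -0.0479, DNA replication and S phase -0.0400, mitosis and G2/M -0.0709, unfolded protein response -0.0900, hypoxia and glycolysis -0.0351, oxidative phosphorylation -0.0120, autophagy and lysosome -0.0662, heat shock -0.0347 and monocyte and macrophage markers 0.0761. Against alone these reversed: Mir680-1 to 0.0306, interferon gamma and antigen presentation -0.0723, JAK-STAT3 targets -0.123, immediate early and AP-1 -0.167, p53 targets -0.0758, DNA replication and S phase -0.0887, mitosis and G2/M -0.0839, MYC targets and ribosome biogenesis -0.0887, unfolded protein response -0.161, hypoxia and glycolysis -0.125, oxidative phosphorylation -0.0982, heat shock -0.150 and monocyte and macrophage markers 0.187. For B cells against alone, medians without B-cell replicate 1 and without B-cell replicate 2 were -0.0896 and 0.106 for DNA replication and S phase, -0.0558 and 0.110 for mitosis and G2/M, -0.133 and 0.0783 for the unfolded protein response, and -0.117 and 0.00976 for oxidative phosphorylation.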

Other observations

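Of the tests below, those of other gene families and of brightness-matched genes were set before their results were seen, and the gene groups and all other tests were chosen after.

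Neutrophil genes were divided by the compartment of the proteins they encode. The 6 genes of specific and gelatinase granules, Ltf, Camp, Ngp, Lcn2, Mmp8 and Mmp9, had a median of 0.49 in neutrophils against alone, from 0.23 to 1.82, with 6 of 6 positive and 2 past the threshold in limma, Ngp and Lcn2. Against B cells their median was 0.39. The 4 genes of azurophil granules, Mpo, Elane, Prtn3 and Ctsg, had a median of 0.18 against alone, where Elane passed, and 0.09 against B cells. The 7 genes of surface receptors and adhesion had a median of 0.03 against alone, from -0.78 to 0.22, and 0.12 against B cells, from -0.82 to 0.52. In each comparison 5 of 7 were positive, and 0 passed over all genes tested. The difference between the groups was not tested.

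Outside the fixed interferon list, Ifi27 rose by 1.20 in neutrophils against alone, Ifi214 by 1.06, Helz2 by 0.54 (adjusted p = 0.0417) and Oas1b by 0.53 (adjusted p = 0.0485), the last pair encoding a helicase and a member of the oligoadenylate synthetase family. Ifi205, of the same p200 family as Ifi214, fell by 0.75. Within the list, Isg15 stood at 0.36 and Irf7 at 0.16 against alone, and neither passed.

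Olfactory and vomeronasal receptor genes were lower in the neutrophil arrays, with a median of -0.37 against alone. Other genes of the same brightness had a median of -0.0793 (95% range of 1000 draws -0.092 to -0.0659). That argues against normalisation that depends on intensity as the whole cause. Such normalisation stays open as a part of the cause, because the matched genes fell too. Genes at or above the median brightness had a median of 0.11 against alone. In 12 of 13 other tissue-restricted families the median was negative, Rhox at 0.04 being the exception. This was the result predicted for a signal shared by genes silent in these cells, such as genomic DNA or non-specific hybridisation. MicroRNA genes at -0.02, predicted genes at -0.08 and the brightness-matched genes fell less than the receptor genes. Such a signal is therefore not shown for dim genes at large. An effect of the co-culture partner cannot be told apart from such a signal, because the B-cell arrays, which share a partner, differed by 0.699 of the difference between neutrophils and alone.

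Lists other than the interferon and neutrophil lists rose against B cells in 14 cases. With the receptor mean as a covariate 4 of 14 kept a positive median, cholesterol and sterol biosynthesis at 0.16, adhesion at 0.03, interferon gamma at 0.01 and MYC targets at 0.00095. The same trend between arrays may therefore underlie most of them. That adjustment rests mostly on the 2 B-cell arrays, which differed most in the receptor mean within a group (5.27 and 5.59). Among brighter genes, whose median was 0.13, only the cholesterol list of the 14 passed. That list was picked from the 14 because it kept its call, also with this covariate, so the intervals take no account of the choice. Its mean was higher than with B cells by 0.31 (95% interval 0.138 to 0.473), and by 0.18 (0.0593 to 0.291) with the covariate. Because of that choice the interval with the covariate cannot decide whether the trend is the whole cause. Against alone the interval with the covariate, -0.0907 to 0.193, includes 0. An effect of the partner cannot be told apart from the trend for the lists together, because the B-cell arrays differed by 0.991 of the difference between the groups in their mean, and all 14 were higher in B-cell replicate 1 than in replicate 2. These values and the result with the covariate draw mostly on the same 2 arrays, so they are not separate support. For the cholesterol list that ratio was 0.366, which leaves an effect of the partner open.

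The mean of the type I interferon list was higher with neutrophils than alone by 0.42 (95% interval 0.343 to 0.488), and by 0.38 (0.149 to 0.612) with the receptor mean as a covariate. This adjustment too rests mostly on the 2 B-cell arrays, where the list means were 7.61 and 7.58. The list was picked for this test after its values were seen, as the one with the largest median, so the intervals take no account of the choice. The lower bound of 0.149 therefore cannot decide whether the receptor trend is the whole cause. With the covariate the list median against B cells fell from 0.48 to 0.26 and 0 single genes passed in limma (8 against alone and 10 against B cells were higher at an unadjusted p under 0.05). The median difference of the 11 called genes against alone went from 0.67 to 0.66 and their median SE from 0.10 to 0.20. For the 4 against B cells these went from 0.92 to 0.87 and from 0.10 to 0.13. Neutrophil RNA carried into the sorted cells cannot be told apart from a response of the myeloma cells: 7 neutrophil genes had a median of 0.403 and 3 of 7 passed. Of these, S100a8, Ngp and Camp lay below the lower quartile of both alone arrays, where differences are compressed, so their size decides nothing. S100a9, Ltf, Lcn2 and Lyz2 lay above it in every array, with differences of 0.15, 0.23, 0.68 and 0.38. Only Lcn2 among them passed, so these brighter genes were not alike and do not settle it either. Mean levels with neutrophils and alone were 6.19 and 5.58 for S100a8, 7.51 and 7.36 for S100a9, 7.48 and 5.66 for Ngp and 7.58 and 6.90 for Lcn2, and the flow sort is meant to remove neutrophils. A response of the myeloma cells to neutrophils stays open as a hypothesis, and no test here separates it from carried RNA.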
